A study of Mus musculus with 6 samples.

How the data were processed

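The samples were 6 ChIP-seq libraries of mouse embryonic stem cell-derived cardiac progenitors on day 6. Per the labels' protocols, the line expresses a tagged GLI3R when given doxycycline, and the tagged protein was recovered with streptavidin beads. Samples were grouped by their titles. The treatment text in the labels names GLI1 where the titles name GLI3R, and the titles were followed. Per the submitters' processing notes, Bowtie2 2.3.2, SAMtools 1.5, MACS2 2.1.1 and the mm10 build were used. Their settings, and whether the pair of pull-downs of a condition was pooled before calling, are not given in the sources used here. Each condition had 1 deposited peak list, so replicates could not be compared.

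The fold enrichment of each peak is a ratio that the authors deposited, taken at the summit. The −log10 p and −log10 q of each peak are the authors' deposited values. The deposited score column equals 10 times −log10 q without its decimals and was not used further. These values are the authors' own, belong to single peaks and were used to describe, rank and filter peaks within a list. Coordinates are printed counted from 1.

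Rows that shared an interval were merged into 1 peak with its best summit, which took 3725 doxycycline rows to 3640 peaks and 4428 untreated rows to 4379. Both lists cover 20 chromosomes. From fold and −log10 p the pileup (fragments over the summit) and the local expectation were worked back, assuming fold = (pileup + 1) / (expectation + 1) and an upper-tail Poisson p. A whole pileup matched within 0.01 of −log10 p for 99.97% of doxycycline peaks and 100% of untreated peaks. The most frequent expectation, taken as background, was 0.368 fragments in the doxycycline list and 0.272 in the untreated list. Whether the input libraries entered the expectation is not stated in the sources used here. Pileups began at 5 and 4 fragments, so most calls rest on few fragments and a small difference between peaks lies within counting error.

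Genes came from a table of 21883 protein-coding genes on GRCm38.p6, the assembly of mm10, which gives gene starts and ends without strand or exons. The design fixed before the data were examined used transcription start sites. Distances to the gene interval (0 inside the gene) replaced them, and either end of a gene replaced the promoter. A GLI motif search and a repeat filter, both planned, need a genome sequence, which was not used here. Exons and introns were not analysed here.

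Overlap was counted from 1 bp and compared with 1000 random placements of the untreated peaks on their chromosomes. Shares have exact 95% Clopper-Pearson intervals. Locations were compared with Fisher's exact test, and medians of shared and list-only peaks with 100000 permutations, two-sided. There were 12 gene lists (255 genes in all), some of which share genes, so their tests are not independent. For each list, the genes with a summit within 50 kb were counted. The count was compared with 10000 random lists that permute membership within 10 classes of the number of neighbouring genes (one-sided permutation p), with Benjamini-Hochberg adjustment over both conditions and all lists. Lists of the same genes were compared between conditions with an exact McNemar test, and, added later, by setting the difference in genes against random lists (two-sided permutation p, Benjamini-Hochberg over 12 lists). A peak within 50 kb of a gene is not thereby assigned to it.

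The genes named were fixed by rule. They are Ptch1, Gli1, Hhip, Gli2 and Gli3, the gene nearest to each of the 12 strongest doxycycline-only, 8 strongest shared and 6 strongest untreated-only peaks by −log10 q (the doxycycline list's for shared peaks), and up to 4 genes per list with the strongest doxycycline peak. A further gene of the rule is not reported here. Alternatives were a −log10 q of at least 5, the top 1000 peaks, other overlap rules, other distances, all rows, other matching and minimum folds or pileups.

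The steps were tested on simulated data. The pileup was recovered for 100% of 2000 simulated peaks. The overlap test, run on 4379 peaks, gave p under 0.05 in 0 of 20 runs on unrelated lists and found 201 shared peaks where 200 were planted. The gene list test, run on 21883 genes, found 100% of planted genes and gave p under 0.05 for 2 of 20 random lists. The test of the difference, on as many genes, gave p under 0.05 for 1 of 20 random lists. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.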

Results

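Binding of the repressor form of GLI3 (GLI3R), the transcription factor that holds Hedgehog target genes down when no ligand is present, was profiled by ChIP-seq. The cells were cardiac progenitors made from mouse embryonic stem cells and collected on day 6. The line carried a tagged GLI3R under a doxycycline-inducible promoter. Cells were either left untreated or given 500 ng/ml doxycycline from day 5, for 24 h. Of the 6 libraries, 4 were pull-downs, with a pair per condition, and 2 were inputs, with 1 per condition. The values analysed were 1 peak list per condition on mm10, so no peak had a replicate error and every test below compares 2 lists, not conditions with replicates. The doxycycline list held 3640 peaks and the untreated list 4379. Fragment totals were not analysed here. The pileup at a summit, worked back from the authors' values, had a median of 7 fragments in the doxycycline list and 5 in the untreated list.

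The first question was whether inducing GLI3R gave binding that the untreated cells did not show, beginning at the genes through which Hedgehog signalling regulates itself. Ptch1, the Hedgehog receptor and a direct GLI target, had 6 summits within 50 kb in the doxycycline list and 0 in the untreated list. Its strongest peak lay inside the gene (chromosome 13, 63566320 to 63566944) with a 17.7-fold enrichment, a −log10 q of 30.1 and a pileup of 25 fragments. A further peak inside Ptch1 (63562837 to 63563410) reached 10.2-fold, and one at 0.234 kb from the end of the gene (63573384 to 63573791) reached 9.93-fold. Gli1, the activator that is itself a GLI target, held 1 doxycycline peak inside the gene (chromosome 10, 127341393 to 127341930) at 8.04-fold. Hhip, which encodes a membrane protein that sequesters Hedgehog ligand, had 2, the stronger inside the gene (chromosome 8, 80049366 to 80049557) at 7.31-fold. Neither Gli1 nor Hhip had an untreated summit within 50 kb. Gli2 and Gli3 differed from these. Gli2 had 1 doxycycline peak at 4.01-fold and 2 untreated peaks, the stronger at 7.07-fold and 41.1 kb away. Gli3 had 0 in both lists. A summit with a pileup as small as 4 fragments, 3.93-fold at background, could enter the untreated list, so a gene without a listed peak is one where that threshold was missed.

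**Figure D1:**
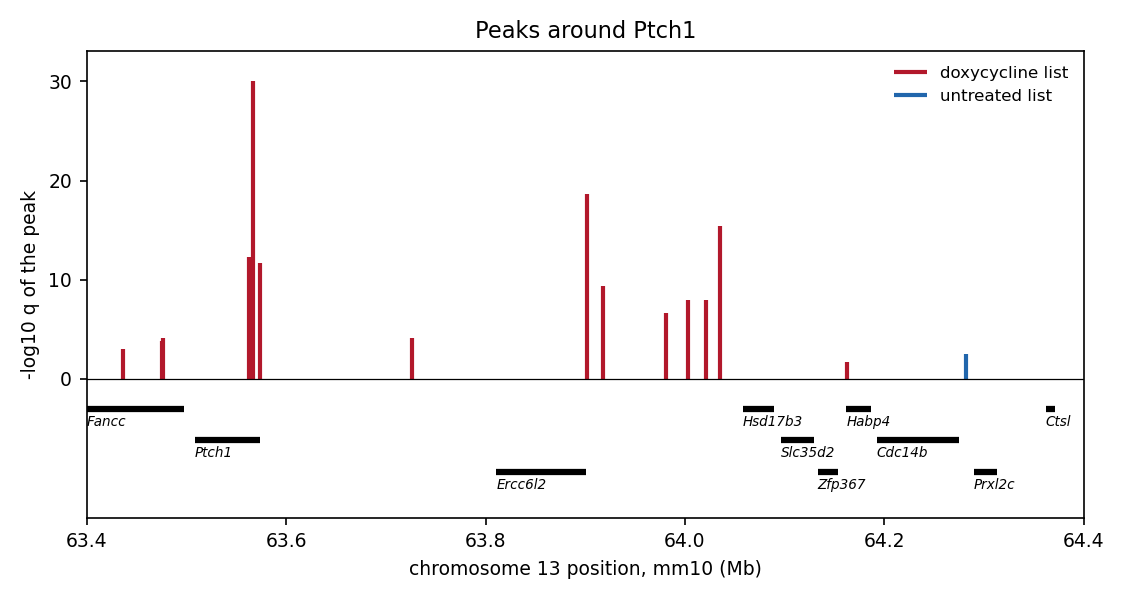
Peaks of both lists around Ptch1 on chromosome 13 (mm10, position in Mb on the horizontal axis), with the −log10 q of each peak as the height of its line (red, doxycycline list; blue, untreated list) and protein-coding genes as black bars below. The tallest line, 30.1, lies inside Ptch1, and a second group of doxycycline peaks lies between Ercc6l2 and Hsd17b3.

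The strongest peaks found only in the doxycycline list lay elsewhere. The highest −log10 q, 80.7, belonged to a 36.5-fold peak inside Arrb1, which encodes beta-arrestin 1 (chromosome 7, 99547701 to 99548165). A 35.1-fold peak lay inside Ccdc146 (chromosome 5, 21353584 to 21353915), and a 30.5-fold peak lay 35.3 kb from Blcap. The fourth, at 28.8-fold (chromosome 4, 147969250 to 147969774), lay 16.2 kb from Nppb and 31.2 kb from Nppa, the natriuretic peptide genes of the heart. Peaks inside Chd3, a chromatin remodeller, and Rnf220, a ubiquitin ligase, were enriched 22.7-fold and 22.5-fold. The next peaks had as nearest genes Pwwp2b (22.0-fold, 32.3 kb away), Wsb1 (21.5-fold, 38.6 kb), Ltbp1 (21.2-fold, 0.521 kb), Gm40369 (21.2-fold, 1.66 kb), Pkdcc (21.1-fold, 105 kb) and the potassium-chloride cotransporter gene Slc12a4 (20.2-fold, 0.983 kb). The strongest peaks found only in the untreated list were weaker by their own list's values. Their nearest genes were Epha3 (14.1-fold, 144 kb away), Mup9 (13.5-fold, 34.5 kb), Aga (13.4-fold, 281 kb), Nbea (11.8-fold, 47.9 kb) and Lcorl (11.8-fold, 494 kb away), with 1 inside Itga11 (12.1-fold).

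The lists had few peaks in common. In the doxycycline list 73 peaks (2.01%, 95% Clopper-Pearson interval 1.58 to 2.52) overlapped an untreated peak by at least 1 bp, and in the untreated list 75 did (1.71%, 1.35 to 2.14). Random placement of the untreated peaks on their own chromosomes gave a mean of 2.22 overlaps and at most 8 in 1000 draws (one-sided permutation p = 0.001, the smallest these draws can give). A block at the start of the chromosome 9 sequence (3000069 to 3038239) held 23 of the 73. There the local expectation was above 2 times background at all 23. Of all 73 shared doxycycline peaks 33 were above that level, against 7 of 3567 doxycycline-only peaks. By the doxycycline −log10 q, the 8 strongest shared peaks were 2 over 1000 kb from Lrrc4c, 1 at 137 kb from Rab10, 1 inside Chl1, 2 in the chromosome 9 block with Alkbh8 as the nearest gene, 1 at 118 kb from Gm2244 and 1 at 29.5 kb from Rpusd4. The local expectations of these 8 ran from 20.6 to 845 fragments. By the untreated −log10 q, the second strongest (3256) was a peak 0.032 kb from Med16, at 664-fold without doxycycline and 14.04-fold with it. Within each list, shared peaks ranked above the others, with the sites of high local expectation included. The comparison was not made without those sites. Their median −log10 q was 7.95 against 3.60 in the doxycycline list and 7.10 against 2.52 in the untreated list, and their median fold was 6.58 against 5.45 and 6.29 against 4.72. In a two-sided permutation test of medians p was 1e-05, the smallest possible, except for fold in the doxycycline list (p = 0.0003).

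The untreated list was the longer at the authors' threshold (doxycycline minus untreated, −739 peaks), and this order depended on the threshold. With a pileup of at least 5 fragments, which every doxycycline peak had, 2855 untreated peaks remained against 3640. With a −log10 q of at least 5 there were 1211 doxycycline and 412 untreated peaks, and with at least 10-fold enrichment 234 and 39. No test of the number of peaks was possible with 1 list per condition.

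Doxycycline-only peaks lay close to gene ends more often than untreated-only peaks. Of 3567 doxycycline-only summits 312 (8.75%, 7.84 to 9.72) were within 1 kb of either end of a protein-coding gene, against 85 of 4304 untreated-only summits (1.97%, 1.58 to 2.44). The odds ratio was 4.76 (Fisher's exact test, two-sided, p = 8.03e-44, with peaks taken as independent). Random placements gave 3.11% (95% range 2.55 to 3.73) for the doxycycline-only peaks and 3.04% (2.53 to 3.55) for the untreated-only peaks, so the first class lay above its range and the second below. Of the 73 shared peaks 2 were near a gene end. Inside genes the shares were 44.5% and 37.8% (Fisher's exact test, two-sided, p = 2.11e-09), against random ranges of 39.3 to 42.6% and 39.1 to 42.0%. The share near gene ends was 4.46% (3.23 to 5.98) among doxycycline-only peaks with a pileup of 5, 16.6% (13.2 to 20.5) at 10 to 14 fragments and 13.04% (7.92 to 19.8) at 15 or more. Among untreated-only peaks it was 2.12% (1.45 to 2.98) at 4 fragments and 3.06% (0.636 to 8.69) at 10 or more. With at least 10-fold enrichment the classes had 31 of 219 and 0 of 26 near a gene end, and the difference did not pass (Fisher's exact test, p = 0.0541). These intervals cover counting error only, and the placements ignore which sequence can be mapped.

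**Figure D2:**
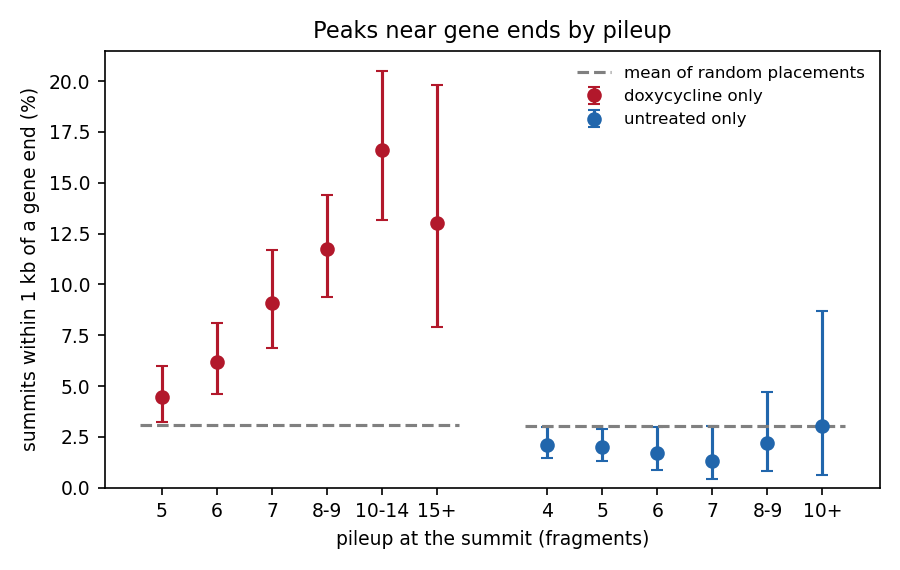
Share of summits within 1 kb of either end of a protein-coding gene (vertical axis, percent) by pileup at the summit in fragments (horizontal axis), for doxycycline-only (red) and untreated-only (blue) peaks. Bars are 95% Clopper-Pearson intervals and the dashed lines are the means of random placements, 3.11% and 3.04%; the red points are at 4.46% at 5 fragments, 16.6% at 10 to 14 and 13.04% at 15 or more.

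The next question was which groups of genes lay near the induced factor's peaks, using 12 lists fixed before the data were examined. Signalling genes, Hedgehog components and regulators known to respond to GLI factors lay near doxycycline peaks more often than matched random genes did. Of 34 BMP, WNT, FGF and Notch genes, 16 had a doxycycline summit within 50 kb against 6.89 expected (adjusted permutation p = 0.0120). Among them were Id1 (13.8-fold, 29.2 kb away) and Id2 (12.5-fold, 0.905 kb), transcriptional targets of BMP. Smad6 (12.8-fold, 20.1 kb) and Smad7 (11.7-fold, inside the gene), inhibitory SMADs that restrain BMP and TGF-beta signalling, were also among them. Of 23 Hedgehog pathway genes, 11 had a doxycycline summit within 50 kb against 4.60 expected (adjusted permutation p = 0.0240). Beside Ptch1, Gli1 and Hhip they included Sufu, an inhibitor of GLI proteins, at 10.1-fold and 12.7 kb away. Of the 11, 4 also had an untreated summit within 50 kb, Gli2 among them. The strongest doxycycline peak at each of these 4 had 5 fragments, the smallest pileup of that list. Of 32 GLI-responsive regulators, 14 had a doxycycline summit within 50 kb against 6.54 expected (adjusted permutation p = 0.0240). The 14 include the neighbouring genes Foxf1, Foxc2 and Foxl1, which share 1 peak of 8 fragments (chromosome 8, 121080753 to 121080955). With list genes within 100 kb of each other counted once, this call was lost, at 12 of 29 genes (adjusted permutation p = 0.0736). The 14 also included Rab34, a GTPase of primary cilium formation (16.4-fold, inside the gene), the cell cycle genes Cdk6 (12.3-fold, inside the gene) and Ccnd2 (10.2-fold, 1.20 kb away), and the survival gene Bcl2 (10.8-fold, 0.336 kb). Of the 14, 4 also had an untreated summit within 50 kb, among them Ccnd2 (7.07-fold, 1.07 kb away) and Bcl2 (3.93-fold, inside the gene). Each p came from 10000 random gene lists, one-sided, adjusted by Benjamini-Hochberg over 24 tests.

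Within 50 kb, none of the 12 lists passed near the untreated peaks. There the same lists had 7 of 34 signalling genes (adjusted permutation p = 0.976), 8 of 23 Hedgehog genes (0.211) and 7 of 32 GLI-responsive regulators (0.976). The difference between the lists, tested gene by gene with an exact McNemar test, did not pass for any of the 12 at the authors' threshold (smallest adjusted p = 0.369). With peaks of −log10 q of at least 5 it passed for the GLI-responsive regulators, with 14 genes against 1 (exact McNemar test, adjusted p = 0.0029). The doxycycline list is the longer at that threshold, and random lists already gave 2.62 genes against 0.803. Set against random gene lists, a test chosen after seeing the data that allows for list length, the difference of 13 genes exceeded the random mean of 1.86 (adjusted permutation p = 0.0012). At that threshold the signalling list (8 genes, adjusted permutation p = 0.0120) and the cardiac progenitor list (7 genes, 0.0292) passed too, the latter not with 1 gene per neighbourhood (0.0789). At the authors' threshold the signalling list alone passed (9 genes, adjusted permutation p = 0.0252), and the GLI-responsive regulators did not (7 genes, 0.0966). With summits within 10 kb none of the 3 doxycycline calls passed (adjusted permutation p = 0.0512 for each). With the nearest gene only, GLI-responsive regulators (15 genes in each list, 0.0182) and Hedgehog genes (9 genes, 0.0348) passed near the untreated peaks. The Hedgehog call near doxycycline peaks was also lost with the nearest gene only (0.0559), with −log10 q of at least 5 (0.0510) and with matching on gene length (0.0582).

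Genes of the heart field had peaks whose group test did not pass. Of 34 cardiac progenitor and second heart field genes 13 had a doxycycline summit within 50 kb against 6.96 expected (adjusted permutation p = 0.0732), and 7 an untreated one. They included Tbx3 (10.2-fold, 18.8 kb away), Hand2 (9.93-fold, 9.51 kb) and Gata6 (9.50-fold, inside the gene), transcription factors of heart development, and Osr1 (7.97-fold, inside the gene). Of the 13, Tbx3, Hand2, Osr1, Foxf1 and Foxc2 are also in the GLI-responsive list, so the calls of these lists are not independent. Foxf1 and Foxc2 share 1 peak. The cardiac progenitor list passed with summits within 100 kb (20 genes, adjusted permutation p = 0.0072), with −log10 q of at least 5 (8 genes, 0.0376) and with the nearest gene only (16 genes, 0.0096). With the nearest gene only it also passed near untreated peaks (17 genes, 0.0096). Of 28 cardiomyocyte genes, 9 had a doxycycline summit within 50 kb and 9 an untreated one (adjusted permutation p = 0.217 and 0.211), and 3 had both. Nppa and Nppb share the peak given above, and Casq2, a calcium store protein, had one at 10.7-fold, 43.7 kb away. The peak 27.1 kb from Ryr2, the calcium release channel, was in both lists, at 28.2-fold with doxycycline and 27.1-fold without.

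Lists of other lineages did not pass in either condition within 50 kb. Endoderm genes had 7 of 16 near doxycycline peaks (adjusted permutation p = 0.117), among them Hhex (6.95-fold) and Gata6, and 3 near untreated peaks. Neuronal differentiation genes had 7 of 20 (0.211), led by Rbfox3 (10.2-fold, 30.2 kb away), and 2 near untreated peaks. Rbfox3 was among the 2, with an untreated peak inside the gene (4.72-fold). The list passed near doxycycline peaks within 100 kb with 12 genes (0.0216). Endothelial and blood genes had 5 of 18 with Sox18 at 6.58-fold, and 7 near untreated peaks (0.172). Paraxial mesoderm and sclerotome genes had 3 of 17, among them Meox2 (6.58-fold), and 4 near untreated peaks, with Meox2 again (3.93-fold). Neural progenitor genes had 2 of 26, Pax6 (inside the gene) and Sox2 (26.5 kb away) at 5.12-fold, and 3. Pluripotency genes had 2 of 15, with Lin28a at 7.31-fold, and 2. Housekeeping genes, the reference, had 4 of 20 against 3.96 expected, and 2. Over all 21883 protein-coding genes, 4387 had a doxycycline summit and 4121 (18.8%) an untreated summit within 50 kb.

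**Figure D3:**
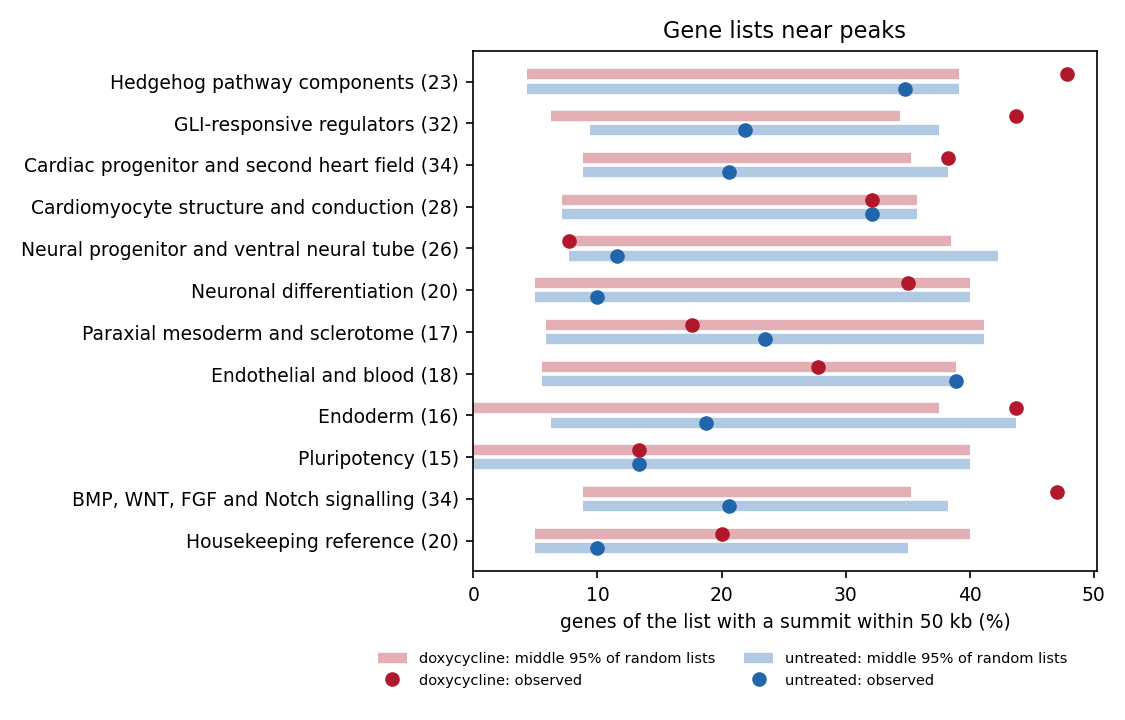
Percent of each list's genes with a peak summit within 50 kb (horizontal axis; number of genes in brackets), for the doxycycline (red) and the untreated (blue) peak list, with bars for the middle 95% of 10000 matched random lists. The red points of the signalling, Hedgehog and GLI-responsive lists, 16 of 34, 11 of 23 and 14 of 32 genes, lie beyond their bars, as do those of the cardiac progenitor (13 of 34) and endoderm (7 of 16) lists, which did not pass after adjustment.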

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

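The alternatives with a minimum fold or pileup, without the chromosome 9 block, with matching on gene length, without shared peaks, with 1 gene per neighbourhood and of differences against random lists were chosen after seeing the data. The GLI motif share with its 5 alternatives and the repeat filter were not run. No paired analysis was possible because each condition had 1 peak list, with no column per replicate. With −log10 q of at least 5 the doxycycline and untreated counts were 1211 and 412, a difference of 799 against −739 at the authors' threshold. With at least 10-fold enrichment they were 234 and 39 (difference 195), with a pileup of at least 10 fragments 599 and 139 (460), and with at least 5 fragments 3640 and 2855 (785). Fewer peaks pass by construction, and the cause of the reversed order is weighed under the other observations. Shared peaks fell to 36 of the doxycycline and 38 of the untreated list both with −log10 q of at least 5 and among the top 1000, with the smallest possible permutation p in each. At 10-fold or more, where 26 untreated-only peaks were left, the differences near gene ends (14.2 percentage points, Fisher's exact p = 0.0541) and inside genes (8.11 points, p = 0.534) kept their direction and did not pass. Of the gene lists, 3 passed near doxycycline peaks within 50 kb, 0 within 10 kb and 5 within 100 kb. With the nearest gene only, 3 passed near untreated peaks. These were cardiac progenitor genes (17 genes, adjusted permutation p = 0.0096) and GLI-responsive regulators (15 genes, 0.0182), both below their random mean in the 50 kb count, and Hedgehog genes (9 genes, 0.0348). The cause was not tested. The difference between conditions passed McNemar's exact test for 1 list with −log10 q of at least 5 and for 0 otherwise. Against random lists it passed for 1 list with all peaks, 3 with −log10 q of at least 5, and 2 when neighbouring genes also counted once. The low pileups limit what absence from a list can show.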

Other observations

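The tests in this part were chosen after the results were seen, except the comparison of untreated-only peaks, and of doxycycline-only peaks of the smallest pileup, with random placements near gene ends. The genes in the next 2 paragraphs were also chosen after their values were seen.

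Of 1167 doxycycline-only peaks with a −log10 q of at least 5, up to 9 fell within 500 kb, on chromosome 13 from 63563184 to 64035214, a stretch with Ptch1 and Ercc6l2. The nearest gene was Ptch1 for 3 of these peaks, Ercc6l2 for 2 and Hsd17b3, which begins beyond the stretch, for 4. Next came 8 in a stretch with Hes1, a Notch effector, on chromosome 16 (29730361 to 30070193). A stretch on chromosome 8 (120827778 to 121301131) with Mthfsd and the forkhead genes Foxf1, Foxc2 and Foxl1 held 7. Of all doxycycline summits, 4 lay within 50 kb of Hes1, and the same 1 within 50 kb of each of these forkhead genes. A further 6 lay in a stretch with Smad6, and 4 stretches held 5 each: one with Hmga2, one with Mycn, one with Dusp5, Smc3 and Rbm20, and a gene-dense one on chromosome 10 with Med16. Peaks spread evenly along each chromosome gave a mean of 4.03 for the fullest 500 kb and at most 7 in 1000 draws. Even spread therefore does not account for 9 (one-sided permutation p = 0.001, the smallest possible), and no draw reached 8 either. The stretches with 7 or fewer were not tested, since each draw gave only its fullest 500 kb. The 369 untreated-only peaks of that strength reached 3 against a random mean of 2.61 (permutation p = 0.587); the lists were not tested against each other. Even placement ignores that doxycycline-only peaks favour gene-rich sequence.

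BMP genes made up much of the signalling list's count. Of 12 BMP ligands, antagonists and feedback genes 9 had a doxycycline peak within 50 kb, against 7 of the other 22. In the rest, 4 of 9 WNT, 2 of 7 FGF and 1 of 6 Notch genes did. The hypothesis that the BMP part stands out of the list had p = 0.0299 in Fisher's exact test, and 0.120 after adjustment over the 4 pathways, so it did not pass.

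The untreated list was longer and shared few peaks with the doxycycline list. Untreated-only peaks lay within 1 kb of a gene end in 1.97% of cases, below the random range, which argues against chance pile-ups spread evenly along the chromosomes. Doxycycline-only peaks of the smallest pileup did in 4.46%, above the random mean. The placements ignore which sequence can be mapped, so chance pile-ups spread unevenly are not excluded in either class. The greater length of the untreated list rests on peaks of small pileup. It held 1524 peaks of 4 fragments, a pileup that no doxycycline peak had, and without them 2855 remained against 3640. With at least 10 fragments, a cut that removes peaks from both lists, 139 untreated peaks remained against 599. Whether the lower background let the peaks of 4 fragments in stays open, since fragment totals were not analysed. Untreated-only peaks had on average 8.08 genes within 500 kb against a random range of 8.56 to 9.14, and doxycycline-only peaks 10.9 against 8.75 to 9.33. Base composition and mappability were not tested and stay open, as does a real loss of weak binding.

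There were 3 shared peaks that stood out with at least 15 fragments in both lists and, in the doxycycline list by which they were picked, at most 3 times the background expectation. They were the peak near Ryr2 (chromosome 13, 12131303 to 12134291, 38 fragments in both lists), one 4.46 kb from Sln, a calcium pump regulator (chromosome 9, 53857557 to 53858771, 37 with doxycycline and 39 without), and one at Med16 (chromosome 10, 79908883 to 79909065, 27 with doxycycline and 1188 without). Whether these are repeats that also pile up in the input stays open. The doxycycline expectation was low by selection, and whether it came from the input is not stated. In the untreated list, not used for picking, the expectation was 1.61 times background at the Ryr2 peak, 1.04 at Sln and 2.90 at Med16. The chromosome 9 block had 25.1 times in the doxycycline list. The Ryr2 and Sln peaks were the only 2 of the 50 strongest doxycycline peaks of low expectation in the untreated list. This argues against GLI3R bound without doxycycline at a level near that with it at the strong sites in general. Weaker binding there stays open, since the untreated list holds no pileup under 4 fragments. The count cannot decide on the Ryr2 and Sln sites, where the peaks were 2989 and 1215 bp wide with doxycycline, against a list median of 160. For the Med16 peak, which was not among the 50, GLI3R bound without doxycycline is argued against by a pileup 44 times as high without doxycycline as with it. Stray DNA with fixed ends also stays open for the Ryr2 and Sln peaks, whose starts and ends differed by at most 47 bp between the lists, since any source common to both would give like ends.

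The shared peaks in the block at the start of chromosome 9 had a median local expectation of 25.1 times background. Repeated sequence that piles up in the input too would give this, if the input libraries entered the expectation. Repeat annotation was not used here, and no biological explanation was tested.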
